A study of Mus musculus with 96 samples.

How the data were processed

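The starting points were 2 tables deposited by the authors, each with 48795 genes and the 96 libraries. The first holds the authors' read counts per gene, in integer counts, and the second the authors' FPKM values. Per the submitters' protocol notes, total RNA was extracted with Qiagen RNeasy kits and libraries were made with a TruSeq stranded protocol. Per the submitters' processing notes, reads were aligned with STAR 2.7.5c to GRCm38 (mm10), handled with SAMtools 1.10 and counted with HTSeq 0.12.3. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap others or have near-identical copies are called uncertain. Coordinates come from GENCODE release M21 on GRCm38, which held 48435 of the gene identifiers, 48349 of them on the same chromosome as in the deposited table. The deposited FPKM values equal the count divided by a fixed length per gene and by the column total.

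Genotype, tissue, sex and animal number were taken from the submitters' labels, which give the Q140 mice as heterozygous and do not state what the prefix of the animal number means. Sex labels matched expression from the inactive X chromosome in 96 of 96 libraries. Cortex and striatum were paired by the animal number that the labels give for both. Across 16806 genes, which are not independent replicates, the median r between the residuals of the same animal's tissues was 0.144 (-0.06 to 0.263 over 48 animals), against -0.003 for other animals, and 37 animals matched best with their own other tissue.

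Each tissue was fitted with its 48 libraries by edgeR 4.0.16 quasi-likelihood (R 4.3.3) with TMM scaling, a term for each of the 6 genotypes and sex as a covariate. Genes were kept by filterByExpr (minimum count 10 in at least a group of 8 libraries, minimum total 15). Comparisons were contrasts of this fit. The Q140 effect in Msh6-/- or Msh6+/- mice minus that in Msh6+/+ mice was the interaction. The sex difference came from a fit of genotype by sex, and the tissue difference from a fit of all 96 libraries, of which 18440 genes were tested; that fit was repeated with the animal as a replicate block. Adjusted p is Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Errors after ± are SE for log2 fold changes and SD over mice for CPM. These comparisons, alternatives and naming rules were fixed before the data were examined. Alternatives were an adjusted p of 0.1, RLE scaling, no filter, DESeq2 1.42.0, no sex term, the animal number prefix as a covariate, only the libraries of the 2 groups, and limma-trend (limma 3.58.1) on log2 FPKM plus 0.1 or 1 for genes with a mean FPKM of at least 0.1. DESeq2 leaves genes under a mean count that it sets per comparison without an adjusted p. In cortex this left 882 of 17622 genes with one for Q140 against wild type and 2590 for Q140 Msh6+/- against Msh6+/- mice, so a gene without one is not a lost call.

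Genes are named by a fixed rule. Msh6 and Htt are followed throughout. For Q140 against wild type in each tissue the 8 largest rises and 8 largest falls by log2 fold change among called genes with a mean log2 CPM of at least 1 are named, and for other comparisons the 5 largest each way. For each gene list with a called member up to 4 members with the smallest adjusted p are eligible. Predicted and clone-named genes are counted but not named, apart from Gm2420. Some genes that the rule selects are not reported here.

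The 26 gene lists (398 genes), written from general knowledge, were: striatal projection neuron identity, D1-type, D2-type, interneuron, cortical glutamatergic, thalamic and septal neurons, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, pericyte and fibroblast, choroid plexus and ependyma, blood, immediate early genes, Polycomb-silenced developmental transcription factors, clustered beta protocadherins, DNA mismatch repair, p53 targets, interferon response, cholesterol synthesis, heat shock and chaperones, oxidative phosphorylation, synaptic vesicle, glutamate receptors, and potassium and sodium channels. They were tested with limma camera at a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of a comparison. A list test with the preset correlation can call small shifts, so both are printed.

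The signature score takes genes called in 1 pair of groups fitted alone, and scores mice of 4 other groups as the mean over genes of the direction times log2 CPM (prior count 1) minus the wild-type mean. At least 20 genes were required. Tests are exact two-sided permutations over the 12870 splits of 8 against 8 mice, or over pairs of such splits for a difference of effects, with a smallest possible p of 0.00016 for a single split. The 95% intervals of single comparisons invert the exact test over shifts of 1 group, and those of a difference of effects come from permuted residuals. The latter replaced an earlier method after that was seen, and the p-values did not change. With the animal number prefix, the interval is that of the linear model. Genes near Msh6 or Htt were compared with all others by Fisher's exact test in a window of 10 Mb. Chance splits of the mice, 100 per comparison including the real grouping, used limma voom.

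Recovery was tested on simulated counts in which 200 genes were changed, 50 at each of 1.25, 1.5, 2 and 4-fold. With edgeR, Q140 against wild type recovered 64%, 86%, 94% and 100% of them in striatum (9 false among 181 calls) and 74%, 90%, 92% and 100% in cortex (10 among 188). The interaction with Msh6-/- recovered 42%, 80%, 90% and 100% in striatum and 54%, 60%, 92% and 96% in cortex. The sex difference recovered 32%, 54%, 76% and 86% in striatum and 20%, 66%, 78% and 96% in cortex, and the tissue difference 42%, 72%, 86% and 94%. Counts of 0 therefore leave room for differences of 1.25-fold and 1.5-fold. Some differences of 2-fold were missed too, most often in the sex tests. Both sex tests and the cortical interaction also missed some differences of 4-fold. The interaction with Msh6+/- was not simulated. With 200 genes changed at once the adjusted threshold is easier to pass, so recovery can be lower where few genes differ.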

Results

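The data are RNA sequencing counts from the cerebral cortex and striatum of 48 mice on a C57BL/6 background, killed at 6 months of age, giving 96 libraries. The mice carried 1 of 6 genotypes: wild type; Q140, heterozygous for a knock-in allele of the Huntington's disease gene Htt with an expanded CAG repeat; Msh6+/- or Msh6-/-; or Q140 together with either Msh6 genotype. Each genotype had 8 mice, 4 males and 4 females, and every mouse gave both tissues. Msh6 encodes a subunit of a DNA mismatch recognition complex, and the cross asks how losing it changes the transcriptional effect of Q140. The total count per library ran from 12.4 to 22.89 M counts (mega). Group means lay between 17.54 ± 2.83 M (SD, n = 8) in Q140 Msh6+/- striatum and 20.71 ± 1.54 M in Msh6+/- cortex. After filtering, 17503 genes were tested in striatum and 17622 in cortex.

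Msh6 transcript (ENSMUSG00000005370, chromosome 17, 87975062 to 87990892, GRCm38) followed the genotype labels. In striatum it fell from 17.3 ± 1.28 CPM (counts per mega-count, TMM-scaled; SD, n = 8) in wild-type mice to 13.8 ± 1.30 in Msh6+/- mice and 8.09 ± 1.32 in Msh6-/- mice. The log2 fold changes were -0.33 ± 0.06 (SE, adjusted p = 0.0367) and -1.1 ± 0.07 (adjusted p = 1.05e-17). On the Q140 background it fell from 19.0 ± 0.783 to 13.9 ± 0.841 and 8.19 ± 0.762 CPM (adjusted p = 4.77e-05 and 1.31e-19). In cortex it fell from 19.5 ± 0.869 CPM in wild-type mice to 14.1 ± 1.04 and 8.83 ± 0.787 (adjusted p = 2.85e-09 and 2.61e-24). With Q140 it fell from 20.2 ± 1.1 CPM in Q140 mice to 13.4 ± 0.781 and 8.24 ± 0.555 (adjusted p = 4.10e-13 and 8.09e-27). Reads were therefore still assigned to the gene in every Msh6-/- mouse, with fold changes of 0.408 to 0.467 against matched Msh6+/+ mice. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) fell slightly with Q140 in striatum, from 240 ± 7.73 to 220 ± 7.88 CPM, a log2 fold change of -0.12 ± 0.03 (adjusted p = 0.00546). Its log2 change was -0.05 on the deposited FPKM scale. It also fell with Q140 in the striatum of Msh6+/- mice (-0.14 ± 0.04, adjusted p = 0.00203) and Msh6-/- mice (-0.11 ± 0.04, adjusted p = 0.0106), with -0.076 and -0.038 on the FPKM scale. In cortex the change passed the test in Msh6+/- mice alone (-0.14 ± 0.03, adjusted p = 0.0465), against -0.08 ± 0.03 in the other two pairs (adjusted p = 0.627 and 0.789). None of the 8 comparisons of Msh6 genotypes in the 2 tissues called Htt.

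**Figure D1:**
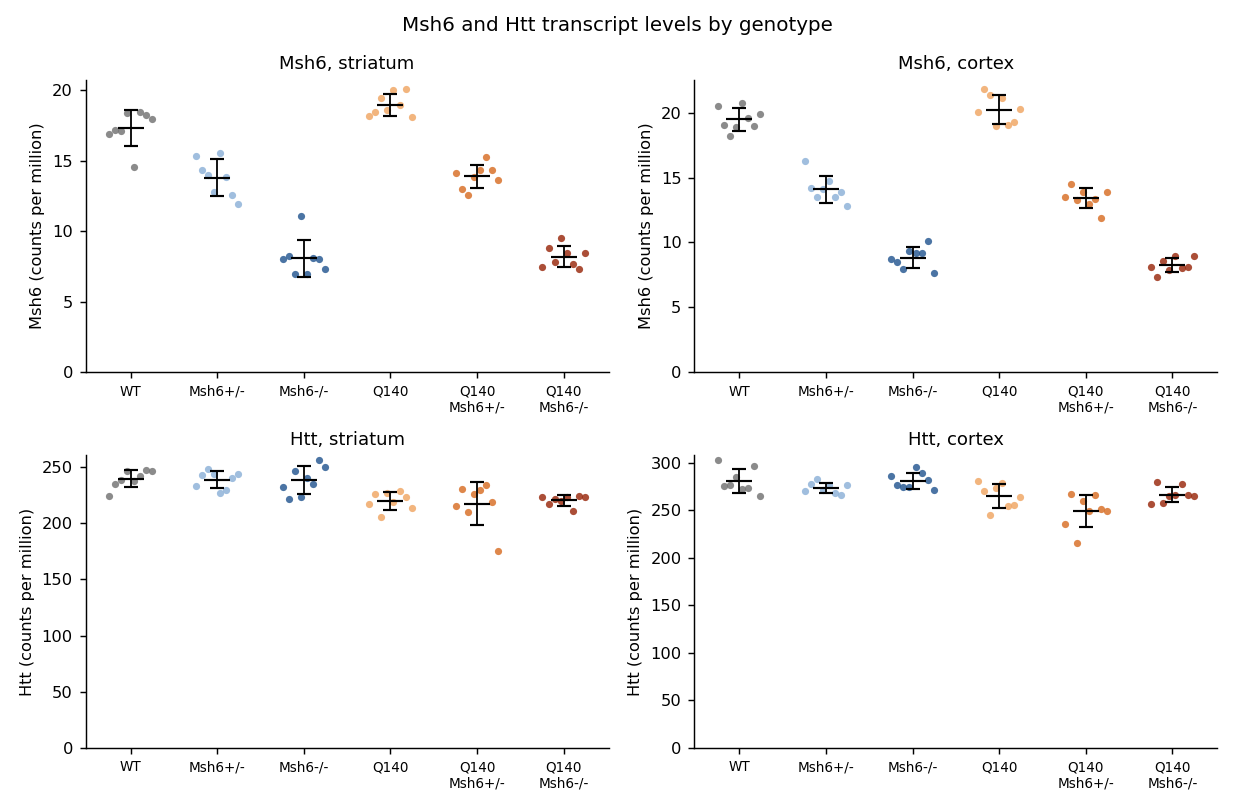
Msh6 (top) and Htt (bottom) in CPM for each mouse by genotype, in striatum (left) and cortex (right), with black bars for the mean ± SD of 8 mice. Msh6 steps down from wild type to Msh6+/- to Msh6-/- with and without Q140, and striatal Htt is 220 ± 7.88 CPM in Q140 mice against 240 ± 7.73 in wild-type mice.

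Q140 changed the striatum of mice with intact Msh6 broadly, and the genes that define its projection neurons fell together. Penk, the enkephalin precursor, fell from 1804 ± 131 to 733 ± 24.8 CPM (SD, n = 8), a log2 fold change of -1.30 ± 0.04 (SE, adjusted p = 2.56e-29). Scn4b, a sodium channel beta subunit, fell from 2425 ± 165 to 1083 ± 35.4 CPM (-1.16 ± 0.04, adjusted p = 1.74e-28). Adcy5, an adenylyl cyclase downstream of dopamine receptors, fell from 2209 ± 87.7 to 1373 ± 38.9 CPM (-0.69 ± 0.03, adjusted p = 4.92e-24). Sfmbt2, which encodes a Polycomb group protein, rose from 2.45 ± 0.660 to 9.70 ± 1.74 CPM (1.98 ± 0.12, adjusted p = 1.46e-18). In total 2719 genes rose and 2482 fell, 29.71% of the genes tested. Which side was larger depended on scaling, since RLE factors called 2440 higher and 2646 lower. Most changes were small, since 60 of the genes that rose and 101 of those that fell changed more than 2-fold. With limma-trend on the deposited FPKM values the share of higher calls was 78.1% (5370 higher and 1509 lower), and 4156 genes were called by both methods.

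Among genes with at least a mean log2 CPM of 1, the 8 largest rises, led by Sfmbt2, included desmosomal genes: Dsp rose by 1.91 ± 0.30 on the log2 scale (SE, n = 8 per group), Dsg2 by 1.75 ± 0.27 and Dsg1c by 1.51 ± 0.23. Also among them were Tmc3 (1.60 ± 0.16), Fam196b (1.31 ± 0.14) and the protocadherin Pcdh20 (1.27 ± 0.10), with adjusted p-values from 1.51e-14 to 1.56e-06. The 8 largest falls began with Gpx6, a glutathione peroxidase, at -2.28 ± 0.16 (3.02 ± 0.797 against 14.7 ± 3.56 CPM, adjusted p = 2.10e-16). Next was Ddit4l, a stress-induced regulator of mTOR signalling, at -2.15 ± 0.08 (9.22 ± 0.892 against 41.0 ± 5.38 CPM, adjusted p = 7.62e-27). They continued with Sec14l3 (-2.04 ± 0.17), the calcium-dependent membrane-binding protein Cpne9 (-1.97 ± 0.15), the membrane transporter Slc4a11 (-1.85 ± 0.10), the serine protease Tmprss6 (-1.85 ± 0.24), the angiotensin fragment receptor Mas1 (-1.71 ± 0.14) and the proton pump subunit Atp6v1c2 (-1.68 ± 0.23). All 8 Q140 mice lay on the called side of the wild-type mean for each gene named here.

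Of 40 projection neuron identity genes measured, 38 fell and 1 rose over all genes and again adjusted over the list alone, with a median log2 fold change of -0.53 (camera adjusted p = 3.91e-59, and adjusted p = 0.000282 with an estimated correlation). This list holds Drd1, Tac1, Pdyn and Chrm4 of the D1-type list, Drd2, Adora2a, Penk and Gpr6 of the D2-type list, and Scn4b of the channel list. In the D2-type list of striatopallidal neurons, 5 of 8 genes fell and none rose, by edgeR and adjusted over the list alone (median -0.50, adjusted p = 5.33e-07, and adjusted p = 0.00354 with an estimated correlation). Adora2a, the adenosine receptor of these neurons, fell from 458 ± 33.3 to 257 ± 13.1 CPM (SD, n = 8; adjusted p = 3.93e-18). The dopamine receptor Drd2 fell from 260 ± 20.6 to 171 ± 11.6 CPM (adjusted p = 1.11e-15). The D1-type list was mixed: 4 of 9 genes fell and 3 rose, over all genes and adjusted over the list alone (median -0.16, adjusted p = 0.115). Drd1 fell by 0.63 ± 0.04 on the log2 scale and the muscarinic receptor Chrm4 by 0.62 ± 0.04, while the transcription factor Isl1 rose by 0.41 ± 0.06.

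Genes for excitability also fell. In the list of potassium and sodium channels, 11 of 15 genes fell and none rose, with the same counts adjusted over the list alone (median -0.25, adjusted p = 3.41e-13, and adjusted p = 0.00354 with an estimated correlation). Kcnh4 fell by 0.86 ± 0.06 (SE, n = 8 per group), Kcnab1 by 0.54 ± 0.04 and Kcnj4 by 0.42 ± 0.04. Of 14 glutamate receptor genes, 10 fell and none rose, or 11 and none adjusted over the list alone (median -0.17, adjusted p = 2.97e-07, and adjusted p = 0.00995 with an estimated correlation). They included the kainate receptor subunit Grik2 (-0.55 ± 0.04). The synaptic vesicle list split, 5 of 16 genes rising and 3 falling, also adjusted over the list alone (median 0.02, adjusted p = 0.401). Synaptophysin, Syp, rose from 445 ± 21.2 to 622 ± 27.2 CPM (adjusted p = 1.18e-16), and Cplx2, a complexin that clamps fusion, fell by 0.29 ± 0.04. Immediate early genes, which report recent neuronal activity, had 3 falls among 12, or 2 adjusted over the list alone (median -0.39, adjusted p = 0.128), led by Egr2 (-1.505 ± 0.34, adjusted p = 0.000377).

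Clustered beta protocadherins, cell adhesion genes on chromosome 18, rose: 16 of 21 passed the test, or 19 adjusted over the list alone, and none fell (median 0.52, adjusted p = 2.05e-10, but adjusted p = 0.0769 with an estimated correlation). Pcdhb19 rose from 17.2 ± 1.55 to 29.1 ± 2.39 CPM (SD, n = 8; adjusted p = 3.10e-14); these genes are near-identical in sequence and lie close together, so their separate counts are uncertain. Only 6 of 46 developmental transcription factors silenced by Polycomb in adult neurons passed the expression filter. A silenced gene can pass it by rising in some genotype, so the list as a whole is not judged here. Among the 6, Wt1 stood at 1.503 ± 0.616 CPM in Q140 mice against 0.0430 ± 0.0441 in wild-type mice (adjusted p = 3.44e-13), and Onecut1 at 0.629 ± 0.239 against 0.0272 ± 0.0417 CPM (adjusted p = 4.82e-09). Of 20 DNA mismatch repair genes 6 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.0171, but adjusted p = 0.186 with an estimated correlation). Msh3, a mismatch recognition protein, rose by 0.18 ± 0.05, and Rfc5, a clamp loader subunit, fell by 0.55 ± 0.07.

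Some markers of other cell types also fell. Microglial genes fell in 9 of 12 cases, or 10 adjusted over the list alone (median -0.19, adjusted p = 0.000607, but adjusted p = 0.151 with an estimated correlation), for example Csf1r by 0.21 ± 0.04. Of 12 astrocyte genes 5 fell, or 6 adjusted over the list alone (median -0.14, adjusted p = 0.00488, but adjusted p = 0.152 with an estimated correlation), including the glutamate transporter Slc1a2 (-0.27 ± 0.03). Of 12 endothelial genes 5 fell, also over the list alone (median -0.20, adjusted p = 0.00488, but adjusted p = 0.152 with an estimated correlation). None of these genes rose. Some lists were not called. Oligodendrocyte genes fell in 4 of 12 cases (median -0.10, adjusted p = 0.168), precursor genes in 1 of 10 (-0.06, adjusted p = 0.152), and pericyte and fibroblast genes in 2 of 10 (-0.09, adjusted p = 0.075), with the same counts adjusted over the list alone. The neuronal lists were interneuron (2 of 13 fell, 1 adjusted over the list alone, median -0.11, adjusted p = 0.198), cortical glutamatergic (4 of 11 rose and 1 fell, also over the list alone, 0.18, adjusted p = 0.225) and thalamic and septal neurons (1 of 8 fell, none adjusted over the list alone, -0.06, adjusted p = 0.601). The choroid plexus and ependyma list (median 0.23 over 7 genes, adjusted p = 0.718) and the blood list (1.66 over 4 genes, adjusted p = 0.366) had no called gene.

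Pathway lists tied to general stress stayed below the threshold. Oxidative phosphorylation had 5 of 18 genes rising and 1 falling, or 7 and 1 adjusted over the list alone (median 0.06, adjusted p = 0.115), with Atp5b, a catalytic subunit of ATP synthase, up by 0.12 ± 0.02. Among 18 cholesterol synthesis genes 3 fell and 1 rose, also over the list alone (median 0.02 and mean -0.01, adjusted p = 0.761), including the master regulator Srebf2 (-0.16 ± 0.03, SE, n = 8 per group). Of 14 p53 targets 2 fell and 1 rose, also over the list alone, and the test pointed down although the median was 0.005 (adjusted p = 0.812); the cell cycle inhibitor Cdkn1a fell by 0.56 ± 0.16. Heat shock and chaperone genes had 1 rise among 12, Hspa8 by 0.19 ± 0.06, and none adjusted over the list alone (median -0.08, adjusted p = 0.812). The interferon response had 1 among 16, and none adjusted over the list alone (median 0.07, adjusted p = 0.835). No called list changed the sign of its median under RLE scaling or on the FPKM scale.

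**Figure D2:**
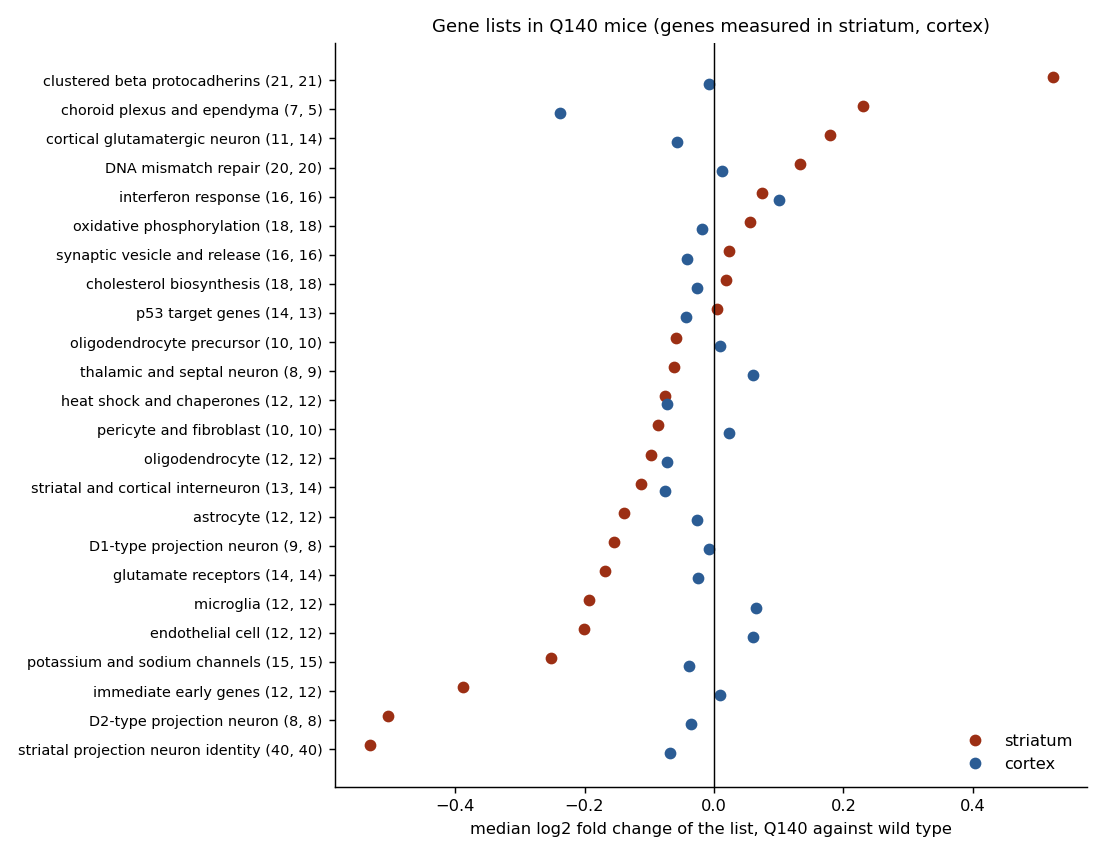
Median log2 fold change of 24 gene lists in Q140 against wild-type mice, in striatum (red) and cortex (blue), 8 mice per group; the blood list, with 4 genes, and the Polycomb list, with 6 of 46 genes past the filter, are left out. Striatal medians run from -0.53 for projection neuron identity genes to 0.52 for beta protocadherins, and the cortical medians of the same lists are -0.07 and -0.01.

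The same neuronal programme fell with Q140 in the striatum of mice lacking Msh6. Against Msh6-/- mice, Q140 Msh6-/- mice had lower Penk (747 ± 49.4 against 1797 ± 111 CPM, SD, n = 8; log2 fold change -1.27 ± 0.04, adjusted p = 4.07e-29), Scn4b (-1.32 ± 0.04, adjusted p = 9.96e-31) and Adcy5 (-0.77 ± 0.03, adjusted p = 2.63e-26). The phosphodiesterase Pde1b fell by 0.69 ± 0.03. Sfmbt2 rose by 2.03 ± 0.12 and the desmosomal Dsg2 by 1.90 ± 0.27, and the falls included Gpx6 (-2.55 ± 0.17), Cpne9 (-2.33 ± 0.16), Ddit4l (-2.23 ± 0.08), Sec14l3 (-2.18 ± 0.17) and Vwa7 (-1.98 ± 0.15). In all 3118 genes rose and 2658 fell, 33% of those tested (2838 higher and 2835 lower with RLE factors). Of these, 1988 higher genes were also higher in Q140 against wild-type mice, where 484 would be shared by chance, and 1953 lower genes were shared where 377 would be, with 2 called in opposite directions; the 4 groups share no mouse. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.76 and Spearman's rho 0.726. Identity genes fell in 38 of 40 cases (median -0.57, camera adjusted p = 1.91e-55, and adjusted p = 0.000472 with an estimated correlation). Oligodendrocyte genes fell in 9 of 12 (-0.34, adjusted p = 1.89e-05, but adjusted p = 0.255 with an estimated correlation). Ttr (5.94 ± 1.19), F5 (2.94 ± 0.66) and Kl (2.42 ± 0.53) were highest in Q140 Msh6-/- mouse 21-3, whose library held 2491 CPM of Ttr, a choroid plexus transcript. Without that library none of the 3 was called (adjusted p = 0.218, 0.913 and 0.219). The choroid plexus gene Clic6 stayed called (0.23 ± 0.08, adjusted p = 0.0208), in a fit that called 5442 of 17593 genes.

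Q140 Msh6+/- mice gave a like picture against Msh6+/- mice. Penk fell from 1693 ± 86.6 to 770 ± 53.2 CPM (SD, n = 8; log2 fold change -1.14 ± 0.04, adjusted p = 5.22e-27), Scn4b by 1.24 ± 0.04 and the regulator of G protein signalling Rgs9 by 0.74 ± 0.03. The rises included Sfmbt2 (1.82 ± 0.12), Fam196b (1.55 ± 0.14), Dsp (1.49 ± 0.31), Rprm (1.43 ± 0.15) and Tmc3 (1.36 ± 0.15). The falls included Gpx6 (-2.42 ± 0.16), Cpne9 (-2.21 ± 0.16), Ddit4l (-2.09 ± 0.08), Vwa7 (-1.94 ± 0.15) and Serpinb1b (-1.85 ± 0.18). In all 2847 genes rose and 2615 fell (31.21%), and the larger side turned with RLE factors (2615 higher and 2737 lower). Identity genes fell in 38 of 40 cases (median -0.54, camera adjusted p = 2.80e-56, and adjusted p = 0.000418 with an estimated correlation). Oligodendrocyte genes fell in 8 of 12 (-0.32, adjusted p = 1.55e-05, but adjusted p = 0.226 with an estimated correlation). Beta protocadherins rose in 15 cases and fell in 1 of 21 (0.48, adjusted p = 3.44e-08, but adjusted p = 0.153 with an estimated correlation).

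**Figure D3:**
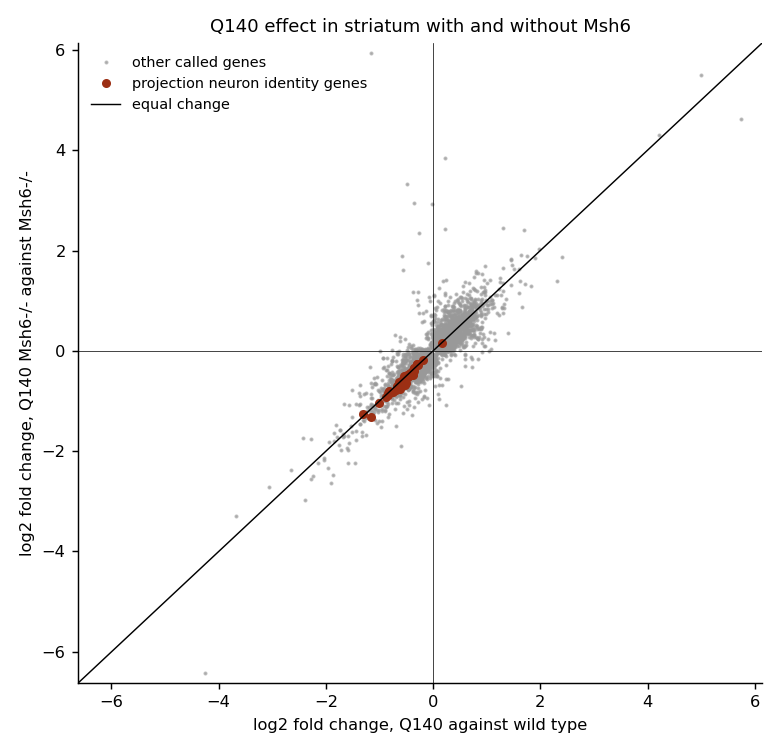
Striatal log2 fold change of each gene called in either comparison: Q140 against wild type (x axis) and Q140 Msh6-/- against Msh6-/- (y axis), 8 mice per group, with projection neuron identity genes in red and the line of equal change in black. Points follow the line, with r = 0.76 across all 17503 genes tested; the highest outlying points above it include Ttr, which is high in the library of mouse 21-3.

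Whether Msh6 loss changes the Q140 effect was tested gene by gene and by a score. No gene passed the edgeR interaction test in the striatum, for Msh6-/- (smallest adjusted p = 0.0651, Dennd1b; 876 genes at an unadjusted p under 0.05; 1 gene with DESeq2) or for Msh6+/- (smallest adjusted p = 0.820, Apba2; 836 genes; 0 with DESeq2), and limma voom gave 0 for both. The signature score of a mouse was its mean log2 expression relative to wild type over 5168 striatal Q140 genes, taken in their direction of change and chosen in Msh6+/- and Q140 Msh6+/- mice, which were not scored. Q140 raised it by 0.2635 in mice with intact Msh6 (95% interval 0.247 to 0.280) and by 0.2902 in Msh6-/- mice (0.277 to 0.304), each with an exact permutation p = 0.00016, the smallest that 12870 splits can give. The Q140 effect was thus larger by 0.0267 without Msh6 (0.0074 to 0.0461), 10.1% of the effect (2.8% to 17.5%), with an exact two-sided permutation p = 0.0113 and 0.0226 after adjustment over 10 tests. Animal number prefixes were not balanced across these groups: they ran from 13 to 21 in wild-type, 14 to 29 in Q140, 14 to 33 in Msh6-/- and 21 to 38 in Q140 Msh6-/- mice. With the prefix in a linear model of the score, chosen after the result was seen, the difference was 0.0247 (95% interval 0.0047 to 0.0448). Q140 Msh6-/- mice scored 0.278 ± 0.0089 (SD, n = 8) and Q140 mice 0.264 ± 0.0123 (exact permutation p = 0.0194, adjusted p = 0.0323). Msh6-/- mice scored -0.0121 ± 0.0155 against 0 ± 0.0178 in wild type (exact permutation p = 0.167, adjusted p = 0.209). Among the lists, oligodendrocyte genes had the smallest p for the striatal difference between Msh6-/- and Msh6+/+ mice, with a median of -0.22 and 4 of 12 lower adjusted over the list alone (camera adjusted p = 1.21e-09, but adjusted p = 0.515 with an estimated correlation). For Msh6+/-, scored over 5370 genes chosen in Msh6-/- mice with and without Q140, the effects were 0.2704 and 0.2614, and their difference of 0.0090 (-0.0151 to 0.0332) did not pass (exact permutation p = 0.477, adjusted p = 0.530). In cortex only 9 and 14 genes qualified, fewer than the 20 required, and no score was computed.

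**Figure D4:**
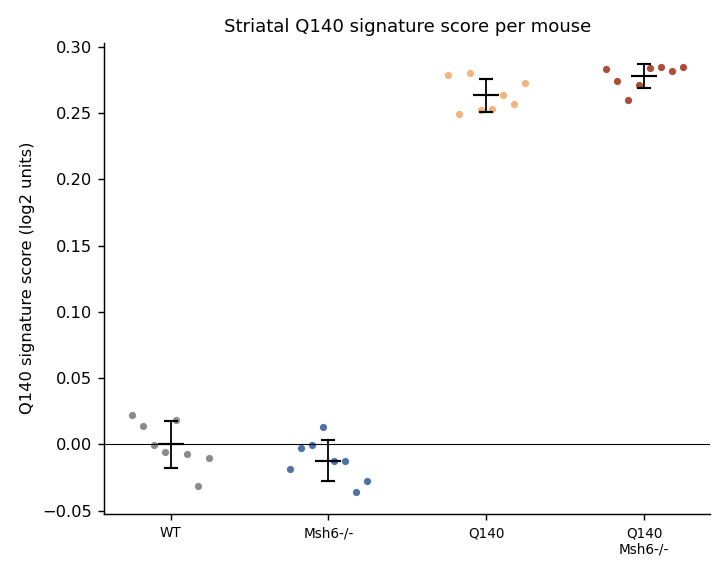
Striatal Q140 signature score (mean log2 units over 5168 genes) for each mouse, with black bars for the mean ± SD of 8 mice per genotype. Q140 Msh6-/- mice average 0.278 ± 0.0089 and Q140 mice 0.264 ± 0.0123, against 0 ± 0.0178 in wild-type and -0.0121 ± 0.0155 in Msh6-/- mice.

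Msh6-/- mice without Q140 differed from wild-type mice in few striatal genes. Nat8f2 (chromosome 6, 85865422 to 85869158), of an N-acetyltransferase family, rose from 0.397 ± 0.149 to 6.83 ± 0.944 CPM (SD, n = 8; log2 fold change 4.08 ± 0.20, adjusted p = 1.54e-21). Ifi203, an interferon-inducible gene, rose by 1.34 ± 0.18 (adjusted p = 3.68e-06), Pcdha1, an alpha protocadherin, by 1.27 ± 0.22 (adjusted p = 0.000793) and Carns1, carnosine synthase, by 0.30 ± 0.06. The rise of Carns1 was not seen between Q140 Msh6-/- and Q140 mice fitted alone (0.051 ± 0.065). Falls besides Msh6 included Rps4l (-0.74 ± 0.14) and Sec24d, a coat protein of secretory vesicles (-0.37 ± 0.07). In all 8 genes rose and 9 fell. Nat8f2, Ifi203, Pcdha1 and Rps4l have close paralogs or overlapping neighbours, so their counts are uncertain. Oligodendrocyte genes had a median of 0.15, with 4 of 12 higher adjusted over the list alone and none over all genes (camera adjusted p = 5.12e-08, but adjusted p = 0.356 with an estimated correlation). Blood genes had a median of 2.62 with 4 of 4 higher over the list alone (adjusted p = 0.000390, but adjusted p = 0.356 with an estimated correlation). This was not seen on the Q140 background, where their median was -0.595 (adjusted p = 0.481; 0.307 on the FPKM scale with 0.1 added), and the median of the difference was -3.29 (adjusted p = 0.033, but adjusted p = 0.843 with an estimated correlation).

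On the Q140 background, Msh6-/- again raised Nat8f2, from 0.528 ± 0.301 to 7.46 ± 0.493 CPM (SD, n = 8; log2 fold change 3.79 ± 0.19, adjusted p = 2.95e-21), and Ifi203 (1.27 ± 0.18). It lowered Rps4l (-0.81 ± 0.14) and Sec24d (-0.33 ± 0.07). Trem2, a microglial receptor gene on chromosome 17 with Msh6, fell by 0.34 ± 0.07 (adjusted p = 0.0325). It was not called between Msh6-/- and wild-type mice in either tissue. Striatal calls were 20 higher and 11 lower, and 7 in each direction were also called between Msh6-/- and wild-type mice, where 0.00914 and 0.00566 would be shared by chance; no mouse is in both comparisons. Ttr (6.36 ± 1.2, adjusted p = 0.00427), the clotting factor F5 (2.88 ± 0.65) and the sugar transporter Slc2a12 (1.59 ± 0.36) were highest in mouse 21-3. Without that library their log2 fold changes were 1.48 ± 0.76, -0.05 ± 0.28 and 0.52 ± 0.18, none of them called. The other 7 mice had 1.785 to 2.661 CPM of Slc2a12, against 1.49 ± 0.216 in Q140 mice. In all 14 genes were called without that library in place of 31, 6 higher and 8 lower, with 13 of them shared. The choroid plexus list had 1 of 7 genes higher, or 4 adjusted over the list alone (median 0.59, camera adjusted p = 9.43e-05, but adjusted p = 0.201 with an estimated correlation). Microglial genes had a median of -0.08 with 1 of 12 lower, also over the list alone (adjusted p = 9.43e-05, but adjusted p = 0.201 with an estimated correlation).

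**Figure D5:**
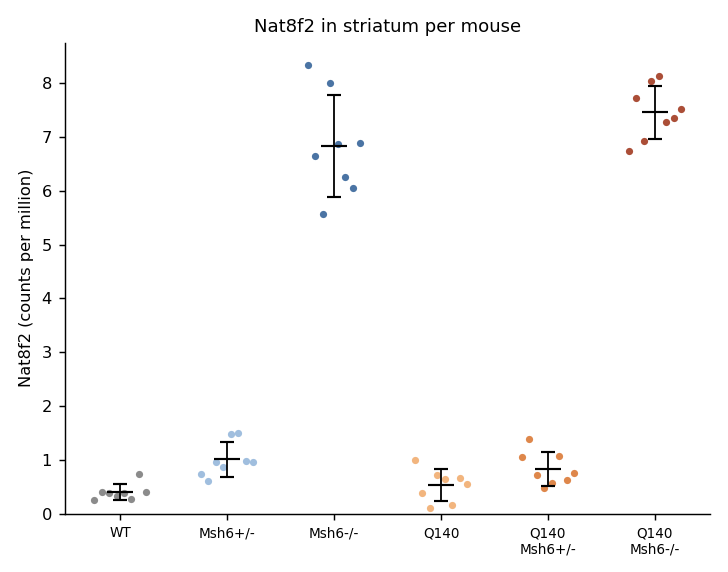
Striatal Nat8f2 in CPM for each mouse by genotype, with black bars for the mean ± SD of 8 mice. Msh6-/- mice average 6.83 ± 0.944 and Q140 Msh6-/- mice 7.46 ± 0.493 CPM, against 0.397 ± 0.149 in wild-type mice.

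Loss of a single Msh6 allele left few genes past the test. In striatum, Msh6+/- against wild-type mice called Nat8f2 (1.01 ± 0.322 against 0.397 ± 0.149 CPM, SD, n = 8; log2 fold change 1.33 ± 0.26, adjusted p = 0.0367) and Msh6. Neither was called with the animal number prefix as a covariate or when fitted on the 2 groups alone. Q140 Msh6+/- against Q140 mice called Msh6 alone, with 992 and 753 genes at an unadjusted p under 0.05. In cortex the first comparison called Msh6, and the second called 2 genes, among them Msh6 (adjusted p = 4.10e-13). Among the lists, striatal oligodendrocyte genes had a median of 0.10 in Msh6+/- against wild-type mice (camera adjusted p = 0.000761, but adjusted p = 0.737 with an estimated correlation). The median was -0.11 in Q140 Msh6+/- against Q140 mice (adjusted p = 1.24e-05, but adjusted p = 0.590 with an estimated correlation).

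Q140 changed few genes in the cortex of mice with intact Msh6. Abhd1, a hydrolase gene, rose from 2.92 ± 0.485 to 6.65 ± 0.720 CPM (SD, n = 8; log2 fold change 1.18 ± 0.10, adjusted p = 1.06e-12). Abca8a, an ABC transporter, rose from 7.07 ± 0.866 to 9.59 ± 1.35 CPM (0.44 ± 0.08, adjusted p = 0.00520). The third call, Gm2420, was higher by 4.45 ± 0.53 (adjusted p = 4.31e-07); it is named because the count is small, chosen after its values were seen. No gene fell, and 1081 genes had an unadjusted p under 0.05. Of 40 projection neuron identity genes none was called, or 2 rose and 6 fell adjusted over the list alone (median -0.07, camera adjusted p = 4.00e-05, and adjusted p = 0.00628 with an estimated correlation). DESeq2, which gave an adjusted p to 882 genes and to none of these 3, called 22, of which 1 was higher and 21 lower.

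In Msh6-/- mice, cortical Q140 again raised Abhd1 (2.76 ± 0.359 to 6.29 ± 0.730 CPM, SD, n = 8; log2 fold change 1.19 ± 0.10, adjusted p = 1.01e-12), Abca8a (0.50 ± 0.08) and the actin-binding Anln (0.45 ± 0.09). Cgref1 rose by 0.37 ± 0.08. Abhd1 and Cgref1 lie within 10 Mb of Htt, so for them DNA linked to the Q140 allele cannot be told apart from the expanded repeat. Q140 lowered Myh7, a myosin heavy chain (-0.51 ± 0.08), Myo5c (-0.50 ± 0.09), Adam33 (-0.50 ± 0.09), Plk5 (-0.48 ± 0.10) and Ddit4l (-0.42 ± 0.09), with 8 genes higher and 16 lower in all. Adam33 was 22.2 ± 3.62 CPM in Q140 Msh6-/- mice, 31.1 ± 2.59 in Msh6-/- mice and 30.6 ± 4.53 in Q140 mice. Its call against Q140 mice, given below, rests on the same Q140 Msh6-/- mice. It was not called in Q140 or Msh6-/- against wild-type mice. In Msh6+/- mice Q140 raised Abhd1 (1.42 ± 0.10, adjusted p = 8.56e-16), Arhgap6 (0.42 ± 0.09), Mrpl33 (0.38 ± 0.05), Anln (0.38 ± 0.09) and Cgref1 (0.35 ± 0.08). It lowered Zfpm2 (-0.34 ± 0.08), Tenm2 (-0.31 ± 0.06), Zmat4 (-0.29 ± 0.06), Atraid (-0.28 ± 0.05) and Sorcs3 (-0.27 ± 0.06), with 13 higher and 21 lower. These last 2 comparisons, which share no mouse, had 7 higher and 5 lower genes in common, where 0.0059 and 0.0191 would be shared by chance. Microglial genes were higher in Q140 Msh6+/- mice, 5 of 12 adjusted over the list alone and none over all genes (median 0.14, camera adjusted p = 1.42e-07, but adjusted p = 0.116 with an estimated correlation). The count for Msh6+/- mice was 145 with DESeq2, which gave an adjusted p to 2590 genes, and 9 when fitted on the 2 groups alone. No cortical gene passed the edgeR interaction test for Msh6-/- (692 genes at an unadjusted p under 0.05; 0 with DESeq2 and limma voom) or for Msh6+/- (smallest adjusted p = 0.0946, Cyb5rl; 911 genes; 1 with DESeq2 and 0 with limma voom).

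In cortex, Msh6-/- against wild-type mice raised Bub1b, a spindle checkpoint kinase, from 2.56 ± 1.57 to 6.82 ± 0.916 CPM (SD, n = 8; log2 fold change 1.38 ± 0.23, adjusted p = 0.000517), Pcdha1 (1.19 ± 0.21), Ifi203 (1.1 ± 0.19), the collagen gene Col5a2 (0.97 ± 0.21) and Rsg1 (0.67 ± 0.12). It lowered Rec8, a meiotic cohesin subunit (-1.12 ± 0.20, adjusted p = 0.00106), Rps4l (-0.93 ± 0.18) and the kinase Prkce (-0.21 ± 0.03, adjusted p = 0.000130). Nat8f2 (4.3 ± 0.25, adjusted p = 7.89e-19) and the oxidoreductase Wwox (0.59 ± 0.05, adjusted p = 9.32e-11) also rose; both are named after their values were seen. In all 14 genes rose and 9 fell. Between Q140 Msh6-/- and Q140 mice 14 rose and 13 fell. The rises included Nat8f2 (3.79 ± 0.23, adjusted p = 1.24e-17; below the expression limit of the naming rule), Pcdha1 (1.40 ± 0.22), Bub1b (1.26 ± 0.23), Eps8l1 (1.15 ± 0.24), Col5a2 (0.97 ± 0.20) and Bglap3 (0.73 ± 0.17). Falls included Rps4l (-0.86 ± 0.17), Adam33 (-0.47 ± 0.09), Ttc7 (-0.36 ± 0.08) and Trem2 (-0.28 ± 0.06, adjusted p = 0.0412). Prkce and Ttc7 lie within 10 Mb of Msh6 on chromosome 17, so for them DNA linked to the Msh6 allele cannot be told apart from loss of Msh6. Trem2 lies on chromosome 17 as well, outside that window. Both comparisons called 10 higher and 8 lower genes in common, where 0.0111 and 0.00664 would be shared by chance, and no mouse is in both.

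Called genes clustered near the engineered genes in some comparisons. Within 10 Mb of Msh6, 4 of 78 cortical genes were called in Msh6-/- against wild-type mice, among them Msh6, Rhoq and Prkce, against 19 of 17491 elsewhere (odds ratio 49.6, 95% interval 12 to 155; Fisher's exact p = 2.99e-06, adjusted p = 1.20e-05 over 4 tests). In striatum 2 of 78 were called, among them Msh6, against 15 of 17369 (odds ratio 30.4, 3.32 to 134; exact p = 0.00257, adjusted p = 0.00343). Msh6 is the edited gene, so its own call was fixed by the design. Without it the cortical odds ratio was 37.2 (3 of 77 genes, Fisher's exact p = 0.000117). The striatal odds ratio without Msh6, 15.2, did not pass (exact p = 0.0684). Within 10 Mb of Htt, 2 of 191 cortical genes were called with Q140, Abhd1 and Gm2420, against 1 of 17378 elsewhere (odds ratio 183, 9.5 to 9840; exact p = 0.000350, adjusted p = 0.000700). In striatum 62 of 191 were called near Htt, 32.46% against 29.75% elsewhere (odds ratio 1.14, 0.823 to 1.55; exact p = 0.426).

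The striatal and cortical effects of Q140 differed for many genes when tested directly. Sfmbt2 changed more in striatum by 2.13 ± 0.18 on the log2 scale (SE, 8 mice per group; adjusted p = 2.94e-17), Dsg2 by 1.72 ± 0.35 and Ipcef1 by 1.40 ± 0.09 (adjusted p = 9.42e-22). In the other direction were Neurod1 (-3.17 ± 1.00, adjusted p = 0.0193), Sec14l3 (-1.97 ± 0.50), Cpne9 (-1.96 ± 0.15), the stress neuropeptide Crh (-1.89 ± 0.41) and Ddit4l (-1.89 ± 0.13, adjusted p = 2.82e-21). In total 2658 of 18440 genes differed, 1370 upwards and 1288 downwards in striatum (14.41%). RLE factors gave 1097 upwards and 1479 downwards, and the fit with each mouse as a replicate block called 3457, of which 2638 were shared. For the lists, lower and higher refer to the Q140 effect in striatum minus that in cortex, not to expression levels. Identity genes were lower in this sense in 31 of 40 cases, or 33 adjusted over the list alone (median -0.47, camera adjusted p = 2.94e-42, and adjusted p = 1.73e-05 with an estimated correlation). Channel genes were lower in 10 of 15 (-0.24, adjusted p = 1.22e-11, and adjusted p = 0.00161 with an estimated correlation). Beta protocadherins were higher in 11 of 21, or 13 adjusted over the list alone (0.56, adjusted p = 7.09e-11, and adjusted p = 0.0474 with an estimated correlation), and in 17 in the blocked fit (adjusted p = 3.29e-05 with an estimated correlation). Glutamate receptor genes were lower in 6 of 14, or 10 over the list alone (-0.12, adjusted p = 1.65e-05, and adjusted p = 0.0474 with an estimated correlation or 0.0786 in the blocked fit). Microglial genes were lower in 6 of 12 (-0.23, adjusted p = 2.22e-05, but adjusted p = 0.0779 with an estimated correlation), and immediate early genes were not called (adjusted p = 0.181) except in the blocked fit (adjusted p = 0.00682, but adjusted p = 0.387 with an estimated correlation).

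Sex did not alter the Q140 effect of any gene in either tissue at the threshold. The edgeR test of the difference between males and females called 0 genes in striatum (smallest adjusted p = 0.679, Acp2; 851 genes at an unadjusted p under 0.05) and 0 in cortex (smallest adjusted p = 0.572, Otof; 1092 genes). There were 4 mice per arm, and DESeq2 and limma voom also called 0. Striatal Q140 calls within each sex were 1426 higher and 1503 lower in males and 1446 higher and 1548 lower in females. Immediate early genes had a male-minus-female median of -0.49 in striatum and -0.48 in cortex (camera adjusted p = 0.00490 and 0.000530), neither with a called gene, and both were lost with an estimated correlation (adjusted p = 0.712 and 0.949).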

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

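The tests of nearby genes, of other-strain DNA, of loss of Msh6 and of choroid plexus tissue used below were chosen after the results were seen.

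The Q140 effect differed between striatum and cortex in 2658 genes, and the Q140 effect on the striatal signature score was larger by 0.0267 in Msh6-/- mice than in Msh6+/+ mice.

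Dixon's test was run on 216 groups of 8 mice and singled out 26 values (12%), while chance singles out about 1 in 20 groups. Library totals stood apart in 3 of 12 groups: wild-type striatum 16-2 with 15.88 M counts (nearest other 18.16), Msh6-/- cortex 14-3 with 22.89 M (20.87) and Q140 Msh6-/- striatum 27-1 with 12.53 M (17.11). Signature scores stood apart in 0 of 8 groups. Named genes stood apart in 23 of 196.

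In striatum, in CPM with the nearest other mouse in brackets, wild-type mice had Msh6 at 14.58 in 16-2 (16.88), Gpx6 at 7.214 in 13-1 (13.74) and Nat8f2 at 0.7344 in 20-2 (0.4101). Q140 mouse 24-1 had Pcdh20 at 21.75 (17.35) and Ttr at 9.023 (2.501). Among Msh6-/- mice, Msh6 was 11.09 in 24-3 (8.241), and 14-3 had Pcdha1 at 9.218 (5.508) and Kl at 4.292 (3.399). Msh6+/- mice had Gpx6 at 25.5 in 18-4 (17.67) and Cpne9 at 22.51 in 26-3 (17.67). Q140 Msh6+/- mice had Htt at 175.1 in 26-4 (210.1) and Sfmbt2 at 10.82 in 15-1 (9.146).

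In cortex, Pcdha1 was 9.772 CPM in Msh6-/- mouse 14-3 (nearest other 3.829), the same animal as in striatum. Col5a2 was 1.922 in wild-type mouse 20-2 (2.686) and 2.117 in Q140 mouse 29-3 (2.915), and Eps8l1 was 9.1 in Q140 mouse 22-2 (5.39). Zfpm2 was 11.58 in Q140 Msh6+/- mouse 16-4 (10.63) and 10.32 in Msh6+/- mouse 23-1 (12.76). Sorcs3 was 76.42 in Msh6+/- mouse 13-3 (65.09).

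Striatum of Q140 Msh6-/- mouse 21-3 held 2491 CPM of Ttr (nearest other of its group 23.13), 67.18 of F5 (1.632), 22.23 of Slc2a12 (2.661) and 127.3 of Kl (4.797). Among the choroid plexus genes, Clic6 was 78.05 CPM there against at most 24.47 in the other 7 mice of its group, and Prlr 40.28 against 0.979. Foxj1, an ependymal regulator, was 11.2 against at most 11.96. If choroid plexus tissue in that library raised these genes, they should lose their calls without it: of 4 members called in Q140 Msh6-/- against Q140 mice, adjusted over the list alone, 0 stayed called. Their median log2 fold change went from 2.51 to 0.07, so the size of their joint rise came from that library. The 4 genes were chosen with it included, so their lost calls cannot exclude a smaller effect of the genotype. Clic6 (0.14 ± 0.08), Kl (0 ± 0.17) and Prlr (-0.14 ± 0.34) lay near 0 without that library. Ttr stayed at 1.48 ± 0.76 without being called, so a rise of Ttr in the other 7 mice is left open.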

How the results depend on the processing

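The fits without mouse 21-3, without Msh6 or Htt itself, without each scored mouse, and of the score with the prefix were chosen after the results were seen. Of 142 alternative counts of called genes 120 stayed within 1.5 times of the first fit. The larger side was not stable: striatal Q140 calls of 2719 higher and 2482 lower became 2440 and 2646 with RLE, 2439 and 2642 with DESeq2, and 2124 and 2424 with no filter. The tissue difference, 1370 higher and 1288 lower, became 1097 and 1479, 1147 and 1533, and 818 and 1297. Striatal Msh6+/- against wild-type calls went from 2 to 0 with the animal number prefix and to 1, not shared, with only the libraries of the 2 groups. Striatal Msh6-/- calls went from 17 to 26 at an adjusted p of 0.1 and 27 with DESeq2. Striatal Q140 Msh6-/- against Q140 calls went from 31 to 50 with no filter, 15 with only the 2 groups and 14 without Q140 Msh6-/- mouse 21-3, with 30, 14 and 13 shared. Cortical Q140 calls went from 3, all higher, to 22 with DESeq2 (1 higher and 21 lower), 7 with the prefix and 1 with only the 2 groups. In cortex, Msh6+/- against wild-type calls went from 1 to 2 with no filter and to 2 with only the 2 groups, and Q140 Msh6+/- against Q140 calls from 2 to 1 with only the 2 groups. Cortical Q140 Msh6+/- against Msh6+/- calls went from 34 to 67 at an adjusted p of 0.1, 145 with DESeq2 and 9 with only the 2 groups, and Q140 Msh6-/- against Msh6-/- calls from 24 to 14 with only the 2 groups, 13 shared. The interaction counts of 0 became 1 at an adjusted p of 0.1 and 1 with DESeq2, for Msh6-/- in striatum and for Msh6+/- in cortex. The cortical sex difference went from 0 to 1 with no filter. DESeq2 left 3 of 3 cortical Q140 calls and 18 of 34 cortical Q140 Msh6+/- calls without an adjusted p; the causes of the other moves were not tested.

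With the animal as a replicate block, the tissue difference called 3457 genes, of which 2638 were shared with the 2658 unblocked calls. Leaving out each mouse in turn gave a signature difference of 0.0233 to 0.0312 and sex difference counts of 0 to 0. Other signature definitions gave 0.0205 to 0.0298, and the prefix as a covariate 0.0247 (0.0085 for Msh6+/-). Without Msh6 itself the odds ratio near Msh6 in striatum was 15.21 in place of 30.41. Msh6 and Htt kept direction in 28 of 28 alternatives, which were RLE and DESeq2. Counts of called lists moved in 40 of 42 alternatives.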

Other observations

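The tests of nearby genes, of other-strain DNA, of loss of Msh6 and of choroid plexus tissue were chosen after the results were seen; the chance splits and the test of a single mouse were written before.

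Some cortical Q140 calls lay on chromosome 5, which carries Htt: 6 of 34 in Msh6+/- mice and 5 of 24 in Msh6-/- mice. In Msh6+/- mice the cortical Q140 calls included Mrpl33, a mitochondrial ribosomal protein (0.38 ± 0.05, SE, n = 8 per group), Cgref1 (0.35 ± 0.08), Atraid (-0.28 ± 0.05) and Htt itself (-0.14 ± 0.03), all on chromosome 5 with Abhd1. Abhd1, Mrpl33, Cgref1 and Atraid were called again in the disjoint Msh6-/- pair. Of 12 calls shared by these 2 pairs, 5 were on chromosome 5 and 7 elsewhere (Abca8a, Anln, Kalrn, Lamp5, Map6d1, Pknox2 and Tmc3). Without Htt itself, 5 of 190 genes within 10 Mb of it were called in each pair, against 28 and 19 of 17378 elsewhere (odds ratios 16.7 and 24.7, Fisher's exact adjusted p = 3.48e-05 and 1.01e-05 over 4 tests). DNA linked to the engineered Htt allele or a local effect of the edited allele predicts such gathering. Neither can be told apart here from an effect of the expanded repeat, and no sequence was examined.

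Blood genes had a cortical median log2 fold change of 2.08 in Msh6-/- against wild-type mice, with 4 of 4 higher adjusted over the list alone (camera adjusted p = 0.000476, but adjusted p = 0.216 with an estimated correlation). On the Q140 background the median was -0.282 (adjusted p = 0.62; 0.45 on the FPKM scale with 0.1 added). Cortical beta protocadherins had a median of -0.16 in the same comparison, with 3 of 21 lower over the list alone (camera adjusted p = 1.72e-06, but adjusted p = 0.216 with an estimated correlation). Cortical immediate early genes had a median of -0.43 with Q140 in Msh6+/- mice (camera adjusted p = 8.53e-05, but adjusted p = 0.500 with an estimated correlation).

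Genes near Msh6 may differ because DNA of another strain came along with the engineered allele. In cortex called genes other than Msh6 gathered within 10 Mb of it, with an odds ratio of 37.21 (Fisher's exact p = 0.000117), with Prkce and Rhoq among them. That gathering prompted the explanation and cannot count for it. In the separate comparison of Q140 Msh6-/- with Q140 mice, the odds ratio without Msh6 was 43.43 in cortex (exact p = 4.74e-06) and 16.5 in striatum (exact p = 0.00772), so the gathering recurred, which DNA linked to the allele predicts. Loss of Msh6 acting on genes irrespective of their place predicts no such gathering. The recurrence in the separate Q140 mice argues against it for the nearby genes as a set. It cannot decide for a single gene such as Prkce or Rhoq. In striatum of mice without Q140, with 1 such gene, the odds ratio of 15.21 (exact p = 0.0684) cannot tell the explanations apart. No sequence was examined for strain variants, and a local effect of the edited allele predicts the same.

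Genes away from Msh6, such as Nat8f2 on chromosome 6 and Wwox on chromosome 8, could follow loss of Msh6, other-strain DNA that segregates independently, or a single mouse. Chosen in mice without Q140, 14 of 15 striatal and 19 of 19 cortical genes moved the same way in the separate Q140 mice, adjusted over these genes. Carns1 was the striatal exception. The result fits loss of Msh6 and argues against DNA that segregates independently. Some of the genes lie close together, in striatum on chromosomes 1, 4, 12 and 18 and in cortex on 4 and 12, so they are not all separate evidence. The ranges of the 16 Msh6-/- and the 32 other mice were separate for only 1 of 15 striatal and 2 of 19 cortical genes. Leaving out any Q140 mouse ended the call of 0 of 14 and 0 of 19, which excludes a single mouse. DNA fixed in the Msh6-/- mice by separate breeding predicts the same and was not tested. Mean animal number prefixes were higher in Msh6-/- than wild-type mice (24.2 against 16.5) and in Q140 Msh6-/- than Q140 mice (27 against 21.9). A difference tied to the prefix could thus recur too. With the prefix as a covariate, 13 of all 17 striatal and 20 of 23 cortical calls without Q140 were kept. With Q140, 22 of 31 and 17 of 27 were kept. In heterozygous mice on the Q140 background 11 of 15 striatal and 17 of 19 cortical genes had the same sign.

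Choroid plexus genes in Q140 Msh6-/- against Q140 striatum were called through the library of mouse 21-3, since 0 of 4 called members stayed called without it. Choroid plexus tissue in that library predicts this. The 4 were chosen with the library included, however, so the lost calls are weak evidence. Their median log2 fold change was 0.07 without that library, against 2.51 with it, so the other mice showed no joint rise of that size. A smaller effect of the genotype is not excluded. For Ttr alone, at 1.48 ± 0.76 without that library (adjusted p = 0.249 over the list alone), a part played by the genotype stays open, since the spread is wide. The choice of members called over the list alone was made after the result was seen.

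Chance splits, 100 per comparison with the real grouping as 1 of them, were judged by limma voom. The rule called chance excluded where fewer than 5 splits reached the real count, with no adjustment over the comparisons. In striatum chance was excluded by this rule for Q140 against wild type (5201 genes, with 1 split reaching that, and at most 2976 in another split). It was also excluded for Q140 Msh6+/- against Msh6+/- mice (5482, 1 split, at most 3501) and Q140 Msh6-/- against Msh6-/- mice (5896, 1 split, at most 3394). The same held for Q140 Msh6-/- against Q140 mice (25, 1 split, at most 2). Q140 Msh6+/- against Q140 mice passed the rule too (1, reached by 2 splits, at most 1). Msh6 was the only edgeR call there, so the splits show nothing about other genes. By the splits alone, chance was not excluded for Msh6+/- (1 gene, reached by 17 splits, at most 88) or Msh6-/- against wild type (20 genes, reached by 5 splits, at most 139). For Msh6-/-, however, 14 of the 17 edgeR calls were made again in the same direction in the separate Q140 mice, where 0.00914 and 0.00566 would be by chance, so chance does not account for those 14. For Msh6+/-, Msh6 itself fell again in the separate Q140 mice (-0.45 ± 0.06, edgeR adjusted p = 4.77e-05), so chance is left open for Nat8f2 and not for Msh6. A split that calls several times the real count points to structure among the mice other than genotype, the source of which was not tested.

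In cortex chance was excluded by the same rule for Q140 against wild type (3 genes, 1 split, at most 2) and Msh6-/- against wild type (22, 1 split, at most 1). It was also excluded for Q140 Msh6-/- against Q140 mice (29, 1 split, at most 1) and against Msh6-/- mice (24, 1 split, at most 4). Msh6+/- against wild type (1, 3 splits, at most 3) and Q140 Msh6+/- against Q140 mice (2, 3 splits, at most 19) passed the rule. Their few edgeR calls include Msh6 itself, so the splits show little about other genes. Q140 Msh6+/- against Msh6+/- mice also passed (32, 2 splits), but another split gave 312, so chance is not called excluded for that count. Of its edgeR calls, 12 were shared with the separate Msh6-/- pair. The split with 312 genes again points to structure among the mice, and its source was not tested either. The tissue difference (2609 genes, 1 split, at most 859) also excluded chance. Interaction and sex counts of 0 were reached by all 100 splits, whose highest counts in striatum were 9 for Msh6-/-, 5 for Msh6+/- and 77 for sex, and in cortex 16, 1 and 1.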
